A study of Mus musculus with 31 samples.

How the data were processed

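Single hepatocytes were prepared from the livers of female C57BL/6J mice by collagenase perfusion and Percoll enrichment, and each cell was picked by hand into a plate well, per the labels' protocols. Smart-seq3xpress, a plate-based full-length cDNA method, was used for amplification by PCR, and a separate TruePrep library was made per cell, per the labels' protocols. Reads were trimmed with Trimmomatic 0.39, aligned with HISAT2 2.1.0 to GRCm38 (mm10) and assigned to genes with featureCounts 1.5.3, per the submitters' processing notes. The gene annotation behind that step is not stated there, nor is the strand setting. The deposited values are whole read counts per gene and cell, not counts of molecules, so PCR copies are included. The deposited table held 40824 genes, 92 ERCC spike-in sequences besides them, and 11477 cells. Among the genes were 0 mitochondrially encoded transcripts.

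The cells belong to 31 libraries of 150 to 602 cells, and each stage or genotype in the labels has 1 library. Every cell column was assigned to a library through the deposited list of raw files per cell, its name had to begin with the name of that library, and 0 were left over. The labels do not name animals, so sums per animal could not be made. All p-values therefore measure only the spread between these libraries, and the number of animals behind a library is unknown. Cells were not used as replicates. No cell was removed in the principal tests, since each deposited cell held at least 5000 genes with a read. Doublets were not called, because cells were picked singly by hand per the labels' protocols, and no clustering was done. The abbreviation HMKO is not spelled out in the labels, and the library names are used as given.

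Reads were summed over the cells of each library. Genes were filtered with filterByExpr, libraries were scaled with TMM, and groups were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. P-values were adjusted with the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. Levels are given as mean CPM ± SD over libraries, with TMM factors taken over all 31 libraries, whereas log2 fold changes come from a fit with TMM factors of its own libraries. A log2 fold change can therefore differ slightly from the ratio of the 2 mean levels.

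Because each stage had 1 library, neighbouring stages stood as replicates of a phase. The wild-type course of 21 libraries was fitted in 6 phases with 15 residual degrees of freedom. These were early gestation (G0, G1.5, G3.5, G5.5), mid gestation (G8.5, G10.5, G12.5), late gestation (G14.5, G16.5, G18.5), P0, lactating (P1L, P2L, P4L, P7L, P14L, P21L) and non-lactating (P1NL, P2NL, P7NL, P14NL). Lactating and non-lactating libraries were also compared on the 4 shared postpartum days with day as a block, which left 3 residual degrees of freedom. The 4 libraries collected after lactation had been stopped at P7 were compared with P4L, P7L and P14L. The Il6st_HMKO and Acss2_HMKO libraries were analysed in a fit of 9 libraries in 6 groups. Its 3 residual degrees of freedom come from the 3 pairs of wild-type libraries of the same stage, and a lone HMKO library was assumed to vary like the other groups.

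A total of 26 lists of genes by pathway or process and 8 lists of cell type markers were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with a correlation estimated from the data. Adjusted p-values of lists are over the lists of a comparison. For single genes of a list, calls were counted over all genes tested and also adjusted over the list alone. Named genes followed a rule. It took the 10 largest and 10 smallest log2 fold changes past the threshold with a mean of at least 20 CPM and no overlap between the groups, or the 5 largest and 5 smallest in the 9-library fit. It left out clone names and pseudogenes. It added up to 3 genes per list with the smallest p past the threshold, and Il6st and Acss2 in every comparison. The groups, tests, lists, the naming rule and most alternatives were fixed before the data were examined. Genes outside the rule are marked as chosen after their values were seen, and not every gene that met the rule is printed. Some genes are not reported here, and the closing section counts gene values without them.

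To compare shares of cells with reads of G2/M genes, each cell was thinned to 337591 reads. The 10329 cells with at least that many reads entered, and 1148 shallower cells were left out. A cell was counted when it had a read of at least 3 of 24 G2/M genes. Shares of single libraries carry exact Clopper-Pearson 95% intervals. The deposited read counts include PCR copies, so reads are not independent molecules and intervals cover counting error only.

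The edgeR comparison designs were tested on simulated data, before use except for Il6st_HMKO at G0 and the difference between its effects, which were simulated after the results were seen. Counts were drawn from the real means and library sizes with 200 genes changed, 100 at 2-fold and 100 at 4-fold. The changed genes were taken only from those with a mean of at least 20 CPM, so the shares below do not cover lower levels. Before the change each gene had 1 mean for all libraries of a fit, without differences by stage, day or cohort. Of the genes changed 2-fold and 4-fold, 53% and 95% were recovered for late against early gestation (21117 genes), and 69% and 98% for lactating against late gestation (21158 genes). The shares were 98% and 100% for lactating against non-lactating (16564 genes), and 56% and 97% for lactation stopped against lactating (16718 genes). In the 9-library fit they were 11% and 99% for G14.5 against G0 (18764 genes), 6% and 78% for Il6st_HMKO at G14.5 (18828 genes), and 2% and 73% for Acss2_HMKO at P4L (18804 genes). They were 7% and 82% for Il6st_HMKO at G0 (18771 genes), and 0% and 2% for the difference (18811 genes), with the change put into G14.5_Il6st_HMKO. Between 2 and 17 unchanged genes were called per simulation.

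Alternatives were the Wald test of DESeq2 1.42.0, DESeq2-style size factors within edgeR, library size as the only scaling, no expression filter beyond 1 count, thinned cells, removal of the tenth of cells with the fewest reads, and each library left out in turn. Further alternatives were a spline over gestation day, fits of only the libraries compared, no day block, all 6 lactating libraries, and cohort as a term. The labels name no cohorts. Cohort here tells libraries with a genotype in their name from those of the course, and the term is 1 shift common to all stages. A filter at a mean of 1 CPM, removal of cells with 10 or more reads of Ins2, the addition of P4L_Acss2_WT to the lactating group, the overlap of DESeq2 calls and a limit of 8 G2/M genes per cell were added after seeing the data. Gene positions are on GRCm38, from the GENCODE annotation, in which 36331 of the 40824 symbols had a single entry. Tables and shuffles were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots with matplotlib 3.10.9. ERCC spike-in reads were not used for scaling, and single-cell clustering was not analysed here.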

Results

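Gene expression was measured in 11477 single hepatocytes of female C57BL/6J mice to follow how these liver cells change through gestation and after birth. The course holds 10 gestation libraries from G0 to G18.5, 1 at P0, 6 lactating libraries from P1L to P21L and 4 non-lactating libraries from P1NL to P14NL. Another 4 libraries were collected 1, 2, 4 and 7 days after lactation had been stopped at P7. A further 6 libraries carry genotype labels: wild type and Il6st_HMKO at G0 and G14.5, and wild type and Acss2_HMKO at P4L. Each had 1 library, so no group of a single stage and cohort had replicates.

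The libraries held 9765832634 reads in all, with a median of 781050 reads and 8172 genes per cell. In gestation the read totals were 209549031 in G0, 180123482 in G1.5, 347010699 in G3.5, 343877965 in G5.5 and 527888862 in G8.5. Later in gestation they were 395647051 in G10.5, 459539553 in G12.5, 326528002 in G14.5, 287057833 in G16.5 and 326320092 in G18.5. After birth they were 255349465 in P0, 297420493 in P1L, 354134726 in P2L, 167202058 in P4L, 570987077 in P7L, 316411758 in P14L and 169964087 in P21L. The non-lactating libraries had 308455617 in P1NL, 341927589 in P2NL, 363506064 in P7NL and 267958864 in P14NL. After lactation was stopped there were 461902409 reads on day 1, 348401575 on day 2, 349683397 on day 4 and 331837896 on day 7. The libraries with genotype labels had 100891798 in G0_Il6st_WT, 142569701 in G0_Il6st_HMKO, 304588120 in G14.5_Il6st_WT, 391214047 in G14.5_Il6st_HMKO, 330829635 in P4L_Acss2_WT and 187053688 in P4L_Acss2_HMKO. Alb, which encodes serum albumin, took the most reads in every library except G10.5, where Apoa2 of high-density lipoprotein did.

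Late gestation was compared with early gestation to ask which hepatocyte genes change as pregnancy advances. Serpina6, which encodes the corticosteroid-binding globulin of plasma (chromosome 12, 103646630 to 103657212, GRCm38), rose from 406.0 ± 77.5 CPM in early gestation (n = 4 libraries) to 21225.5 ± 6382.5 CPM in late gestation (n = 3). Its log2 fold change was 5.68 with a standard error of 0.74 (edgeR quasi-likelihood, adjusted p = 0.000237). Abca17, an ABC transporter gene, and Gpx3, which encodes the plasma glutathione peroxidase, rose by 8.40 and 8.17 on the log2 scale from under 0.2 CPM. Crip1, a LIM-domain protein gene, rose by 6.82 and Dnajc12, a co-chaperone gene, by 4.76. Peg3, an imprinted zinc-finger gene, rose from 5.87 to 107.0 CPM and Nedd9, a scaffold gene of focal adhesions, from 1.47 to 51.0 CPM. In the other direction, Cyp2b13, a female-biased cytochrome P450 gene, changed by -3.66 on the log2 scale and C9, of the terminal complement complex, by -3.54. Abcc3, an exporter of conjugated bile acids, changed by -2.69 and Ddah1, which degrades methylarginines, by -2.58. The amino acid transporter genes Slc7a2 and Slc38a4 changed by -2.02 and -1.99. Ccnd1, the cyclin of the G1 phase, had 10.7 CPM late and 39.5 CPM early (adjusted p = 0.0479, edgeR).

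Hormone receptors and plasma proteins were among the other genes that rose late in gestation. Prlr, the prolactin receptor (chromosome 15, 10177238 to 10349180), rose from 351.8 ± 27.3 to 1845.4 ± 496.5 CPM, and Ghr, the growth hormone receptor (chromosome 15, 3317760 to 3583492), from 497.1 to 4481.3 CPM. Cp, which encodes the copper-binding ferroxidase ceruloplasmin (chromosome 3, 19957054 to 20009145), rose by 2.26 on the log2 scale. Alb rose by 1.38, Serpina1b of the antitrypsin family by 1.33 and Apoc2, the cofactor of lipoprotein lipase, by 2.46. The desaturase genes Fads1 and Fads2 rose from 327.5 to 958.0 CPM and from 38.2 to 125.9 CPM, Cyp8b1 of cholic acid synthesis by 1.55, and Ldha of lactate formation by 1.10. Fgf21, a hormone of the fasting response, rose from 2.13 to 26.2 CPM. Cyp3a44 and Sult3a1, both female-biased drug-metabolism genes, rose by 1.84 and 2.39. Among periportal genes, Gls2 of glutamine breakdown changed by -1.45, Pigr, the transporter of IgA, by -1.08, and Ass1 of the urea cycle by -1.04. Aass and Prodh of amino acid breakdown changed by -1.15 and -1.30, Cyp3a11 of drug metabolism by -1.44, and the hepatic uptake carrier Slco1b2 by -1.10. Il6st, the shared receptor subunit of the interleukin-6 family, had 49.5 CPM late and 45.3 CPM early, and Acss2, which makes acetyl-CoA from acetate, had 129.0 and 234.7 CPM (adjusted p of 0.719 and 0.344, edgeR).

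For late against early gestation, of 22192 genes tested, 610 were higher and 412 lower in late gestation (edgeR quasi-likelihood, adjusted p under the threshold), and 4101 had an unadjusted p below it, with 1110 expected by chance. By list, 6 of 18 periportal genes were lower and 0 higher, 12 did not pass, and 3 had a log2 fold change above 0 (camera, adjusted p = 4.52e-05, and adjusted p = 0.393 with an estimated correlation). The urea cycle and amino acid breakdown list had 7 of 30 genes lower and 1 higher (adjusted p = 0.000436, and 0.393 with an estimated correlation). ER folding had 0 of 24 genes past the threshold and 6 higher when adjusted over the list alone (adjusted p = 0.000106, and 0.393 with an estimated correlation). The STAT5 and growth hormone list had 2 of 11 genes higher (adjusted p = 0.000324, and 0.0578 with an estimated correlation). The acute phase list had 3 of 29 genes higher, Cp, Itih4 and Lbp, with a median log2 fold change of 0.33 but a mean of -0.05. With library size as the only scaling, the calls were 406 higher and 3016 lower, a share of 11.9% higher in place of 59.7%. That scaling moves the median of all genes by -0.38 on the log2 scale, and the medians of the acute phase and STAT5 lists then fall below 0, to -0.06 and -0.20. DESeq2 called 2011 genes. Without G14.5, G16.5 or G1.5 edgeR called 548, 461 or 600 genes, and without cells with insulin reads 598.

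**Figure D1:**
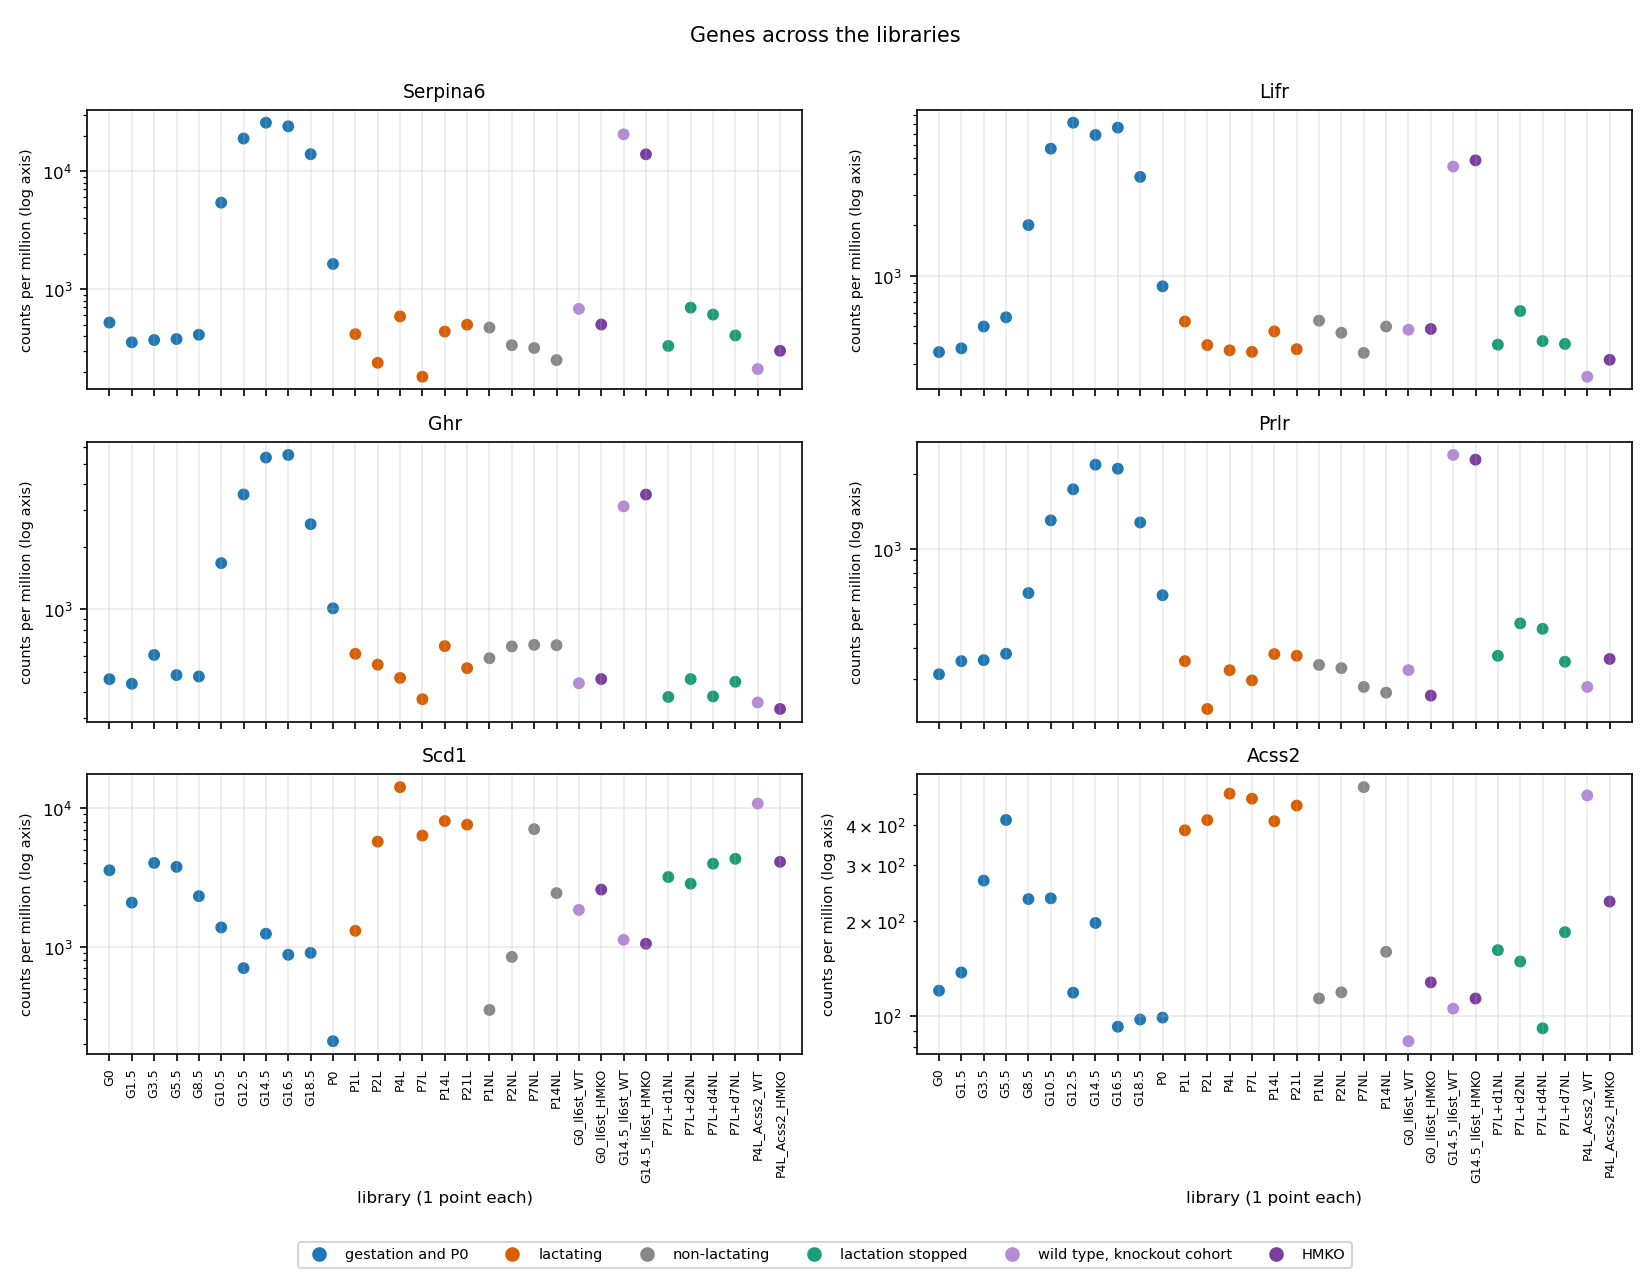
Reads of Serpina6, Lifr, Ghr, Prlr, Scd1 and Acss2 in each of the 31 libraries, in CPM on a log axis. Each point is 1 library, coloured by group, and levels of 0 are not drawn. Serpina6 averages 21225.5 CPM in the 3 late gestation libraries and 393.2 CPM in the 6 lactating ones.

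Lactating libraries were compared with late gestation to ask which genes differ between late pregnancy and lactation. This comparison does not separate lactation from the end of pregnancy itself. Lifr, the receptor of leukemia inhibitory factor (chromosome 15, 7090614 to 7197489), fell from 6107.1 ± 1975.1 CPM in late gestation (n = 3 libraries) to 411.2 ± 73.4 CPM in lactation (n = 6). Its log2 fold change was -3.89 with a standard error of 0.30 (edgeR quasi-likelihood, adjusted p = 6.38e-07). Serpina6 returned to 393.2 ± 155.4 CPM, a change of -5.76, and Abca17 and Crip1 changed by -6.65 and -5.73. Lifr and Serpina6 were low without lactation too. Median Lifr reads per thinned cell were 1001 to 2188 in late gestation and 85.5 to 172 in lactation. They were 178.5 in P0 and 110 to 165 in the non-lactating libraries. Serpina6 had 3630.5 to 7986 in late gestation and 49 to 154 in lactation. It had 219 in P0 and 72 to 166 in the non-lactating libraries. Prlr and Ghr, the prolactin and growth hormone receptors, changed by -2.50 and -3.08. Cp and Itih4, both plasma acute phase proteins, changed by -2.05 and -2.22, and Serpina1e of the antitrypsin family had 1349.4 CPM against 12068.9. Ldha changed by -1.66, Fgf21 by -4.32, and Apoc2 and the lipolysis inhibitor gene G0s2 by -2.01 and -2.06. Scd1, the main fatty acid desaturase of liver (chromosome 19, 44394455 to 44407879), rose from 1009.0 ± 203.9 to 7203.3 ± 4171.3 CPM (adjusted p = 0.0396). Elovl6, which elongates palmitate, rose from 64.4 to 370.8 CPM, Acly, which makes cytosolic acetyl-CoA from citrate, from 159.0 to 519.8 CPM, and Acss2 (chromosome 2, 155517948 to 155585724) from 129.0 ± 58.5 to 442.1 ± 46.1 CPM. Ddah1, C9 and Abcc3, all lower late in gestation, rose by 3.11, 2.73 and 2.67. Il6st had 39.6 CPM in lactation and 49.5 CPM in late gestation (adjusted p = 0.143).

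For lactating against late gestation, of 22192 genes tested, 339 were higher and 569 lower in lactation (edgeR quasi-likelihood). The fatty acid synthesis list had 8 of 19 genes higher and 2 lower, the desaturases Fads1 and Fads2, which changed by -1.16 and -1.31 (camera, adjusted p = 2.67e-07, and 0.192 with an estimated correlation). Periportal genes rose in 9 of 18 cases, with Gls2 at 1.73, Ass1 at 1.28 and Pigr at 1.04 (adjusted p = 1.91e-11, and 0.165 with an estimated correlation). Pericentral genes fell in 6 of 17 cases, among them Lhpp, a phosphatase gene, Gulo of vitamin C synthesis and the glutamate carrier Slc1a2, at -2.20, -1.44 and -2.86 (adjusted p = 3.05e-10, and 0.165 with an estimated correlation). ER folding genes fell in 8 of 24 cases, with the chaperone genes Sdf2l1 and Pdia6 at -1.54 and -0.98 and Calr, another, at 362.5 against 724.9 CPM (adjusted p = 4.39e-12, and 0.165 with an estimated correlation). The fatty acid oxidation list had 3 of 22 genes lower, among them Fgf21 and the thioesterase gene Acot1 (adjusted p = 5.3e-07, and 0.176 with an estimated correlation). The cholesterol synthesis list had 3 of 25 genes higher (adjusted p = 5.14e-06, and 0.406 with an estimated correlation). The STAT5 and growth hormone list, with 3 of 11 genes lower, held with an estimated correlation too (adjusted p of 1.35e-05 and 0.0248). Its mean log2 level was 6.13 to 6.65 in late gestation, 5.54 to 5.94 in lactating libraries and 5.53 to 6.10 in non-lactating ones. The erythroid markers had 1 of 6 genes lower and a median of -3.76 (adjusted p = 9.53e-06, and 0.165 with an estimated correlation). Aass rose by 1.14 and Slc10a1, which takes up bile acids from blood, by 1.31. With library size as the only scaling, 1162 genes were higher and 371 lower, a share of 75.8% higher in place of 37.3%, and the median of all genes moved by 0.23. DESeq2 called 1780 genes, and without G14.5 or G16.5 edgeR called 3.3e+02 or 397.

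Lactating and non-lactating libraries of the same postpartum day were compared to separate lactation from the time since birth. Acss2 averaged 422.9 ± 42.3 CPM in lactating libraries and 229.3 ± 198.3 CPM in non-lactating ones (n = 4 each), and P7NL alone had 525.2 CPM. Elovl6 had 346.2 and 100.4 CPM, Fabp5, a carrier of fatty acids, 579.5 and 188.2 CPM, and Mt1, the metal-binding metallothionein, 1041.1 and 304.4 CPM. Each of these 3 was higher in lactation on 4 of 4 days, at an adjusted p of 0.0941, the smallest of any gene (edgeR quasi-likelihood). Fasn, the fatty acid synthase, had 543.0 and 203.7 CPM, Acly 526.1 and 225.4 CPM, Sqle of cholesterol synthesis 63.0 and 28.3 CPM, and Scd1 5364.8 and 2672.9 CPM. Scd1 was not higher on every day. Its median reads per thinned cell were 2115 in P7L and 2691 in P7NL. On days 1, 2 and 14 they were 308, 1308.5 and 2288.5 in lactating libraries and 94, 280 and 632 in non-lactating ones. For Fasn, Acly and Sqle only the means are given. Cpt1a, which brings fatty acids into mitochondria, had 94.98 and 144.0 CPM. Il6st had 39.0 and 43.5 CPM. Genes of this paragraph other than Acss2 and Il6st were chosen after their values were seen.

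For lactating against non-lactating, of 16869 genes tested, edgeR's quasi-likelihood test called 0 between lactating and non-lactating libraries, with 1517 at an unadjusted p below the threshold and 843 expected by chance. DESeq2 called 251 higher and 173 lower. Fatty acid synthesis had the smallest adjusted p of any list here (camera, 1.49e-26, and 0.57 with an estimated correlation), and 12 of its 19 genes were higher when adjusted over the list alone. In the same way 8 of 25 cholesterol synthesis genes were higher and 11 of 22 fatty acid oxidation genes lower (adjusted p of 1.14e-15 and 3.43e-12, and 0.57 for both with an estimated correlation). Without the day 7 pair of P7L and P7NL, in which the Acss2 level was higher in the non-lactating library, edgeR called 9 genes, Acss2 among them with a log2 fold change of 1.65 (adjusted p = 0.0439). In the 1 simulated run of this design 98% of genes changed 2-fold were called, although Elovl6, with a larger difference in mean level, was not called in the real data.

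Libraries taken after lactation had been stopped were compared with P4L, P7L and P14L to ask what differs after the end of lactation. P4L and P7L are of an earlier postpartum day than any library after the stop, so postpartum age was not matched. Hamp, which encodes the iron hormone hepcidin (chromosome 7, 30942368 to 30944032), rose from 1088.3 ± 792.8 CPM in lactation (n = 3 libraries) to 10148.8 ± 5907.1 CPM (n = 4), a log2 fold change of 3.17 with a standard error of 0.78 (edgeR quasi-likelihood, adjusted p = 0.0375). Its near-identical neighbour Hamp2 rose by 1.87, and reads may be shared between the 2 genes. Hp, which binds free hemoglobin, rose from 1993.8 to 6791.8 CPM, and the plasma proteins Orm3, Lbp and Itih4 rose by 2.01, 1.24 and 0.92. Cyp2e1, the ethanol-oxidising P450 of pericentral cells, rose from 786.7 to 3147.2 CPM and Cyp2c37, another pericentral P450, by 1.32. Ang, a ribonuclease gene, rose from 133.0 to 516.9 CPM and Alas1 of heme synthesis from 85.3 to 249.3 CPM, Nfil3, a clock-controlled repressor, and Cyp2b13 rose by 2.17 and 2.23. Acss2 fell from 464.9 ± 48.0 to 146.4 ± 39.3 CPM (adjusted p = 0.0135), Elovl6 from 461.2 to 101.9 CPM and Fabp5 from 785.7 to 144.0 CPM. The cholesterol synthesis genes Lss, Sc5d and Insig1 changed by -1.53, -1.63 and -1.90. Pklr of glycolysis changed by -1.35, and G6pdx, which supplies NADPH, had 3.05 CPM against 19.1. Srsf2, a splicing factor gene, Dntt, a DNA polymerase gene of lymphocytes, and Ank3, an ankyrin gene, changed by -2.82, -2.19 and -2.06. Ins1, Ins2 and Iapp, the hormone genes of pancreatic beta cells, had some of the most negative log2 fold changes of lactation stopped against lactating, with Ins2 at -12.33, and all 3 were called without P7L too. P7L had 7289 CPM of Ins2, P4L 104.3 and P14L 8.79 CPM, and the 4 libraries after the stop 0.216 to 0.759 CPM.

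For lactation stopped against lactating, of 17233 genes tested, 899 were higher and 933 lower after lactation had been stopped (edgeR quasi-likelihood). The fatty acid synthesis list had 11 of 19 genes lower and 0 higher (camera, adjusted p = 3.22e-10, and 0.485 with an estimated correlation), and cholesterol synthesis 4 of 25 lower (adjusted p = 0.000155, and 0.652 with an estimated correlation). Ribosomal protein genes rose in 22 of 86 cases, led by Rplp1 and Rplp2 of the ribosomal stalk and Rps12, at 0.98, 0.98 and 1.15 (adjusted p = 1.47e-13, and 0.652 with an estimated correlation). Oxidative phosphorylation genes rose in 10 of 79 cases, among them Atp5g3 and Ndufb7, at 0.73 and 0.88 (adjusted p = 1.3e-06, and 0.652 with an estimated correlation). The acute phase list had 7 of 29 genes higher, pericentral 4 of 17, and the endothelial markers 3 of 10 (adjusted p of 0.00113, 5.32e-05 and 1.59e-05, each 0.652 with an estimated correlation). Those markers, the endothelial receptor genes Clec4g, Stab1 and Stab2, rose by 2.07, 1.67 and 1.17 from levels under 5 CPM. The summed level of the endothelial markers was 26.0 to 43.9 CPM after the stop and 8.8 to 16.8 CPM in P4L, P7L and P14L, but 45.1 CPM in P4L_Acss2_WT and 43.2 CPM in P4L_Acss2_HMKO, which lactate too. Igfals and Cish, both targets of growth hormone, rose by 1.18 and 1.65, whereas Bcl6, which STAT5 represses, changed by -0.81. Gapdh of glycolysis, Cpt2 of fatty acid oxidation and Hpd of tyrosine breakdown rose by 1.48, 0.95 and 1.23. The peroxisomal oxidation gene Ehhadh, Slc10a1 and the mitotic kinesin gene Kif20a changed by -1.01, -1.13 and -2.11. Il6st (chromosome 13, 112464070 to 112510086) rose from 39.8 ± 0.872 to 58.3 ± 4.59 CPM (adjusted p = 0.0407). Library size as the only scaling gave 446 higher and 1424 lower, a share of 23.9% higher in place of 49.1%, with the median of all genes moved by -0.19. DESeq2 called 3555 genes, and the labels do not say whether these 4 libraries were made alongside the course. The count fell to 63 without day 4 after the stop, 226 without day 7, 203 without P14L and 662 without P4L, and to 1112 without cells with insulin reads.

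**Figure D2:**
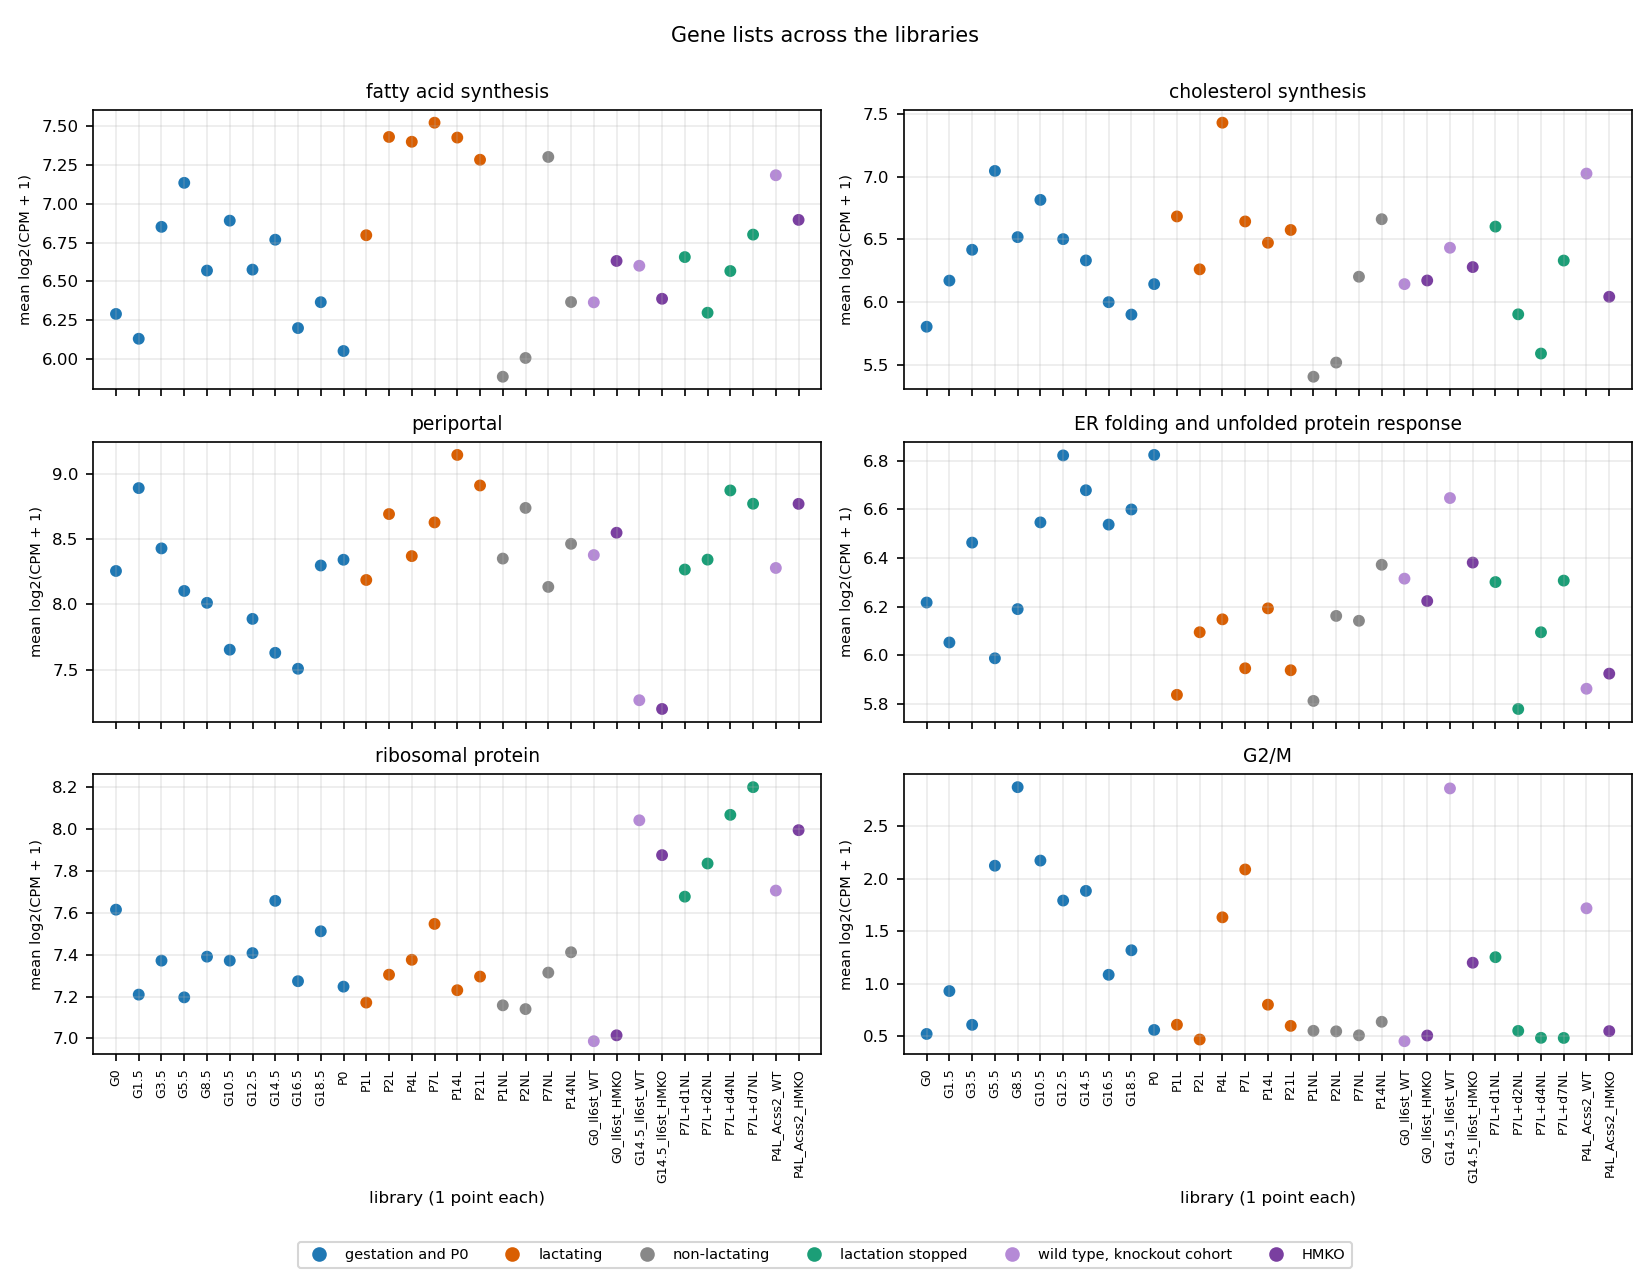
Mean log2(CPM + 1) of the genes of 6 lists in each of the 31 libraries, with 1 point per library coloured by group. The lists are fatty acid synthesis, cholesterol synthesis, periportal, ER folding, ribosomal protein and G2/M. The ribosomal protein level lies between 7.68 and 8.2 in the 4 libraries after lactation was stopped and between 7.17 and 7.55 in the 6 lactating libraries of the course.

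For the genotype libraries the targeted genes are given first. Il6st had 39.8 CPM in G0_Il6st_HMKO, 39.5 CPM in G0_Il6st_WT and 48.5 CPM in G0. At G14.5 it had 48.5 CPM in G14.5_Il6st_HMKO, 54.6 CPM in G14.5_Il6st_WT and 54.8 CPM in G14.5. Acss2 had 229.4 CPM in P4L_Acss2_HMKO, 494.7 CPM in P4L_Acss2_WT and 501.1 CPM in P4L. The labels do not say which part of either gene is deleted, and reads outside the deleted part check nothing. The Il6st levels therefore neither bear out nor contradict the label of the libraries labelled Il6st_HMKO.

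G14.5 was compared with G0 in wild-type libraries of both cohorts, pooled in the same fit. The cohorts were not tested apart. The course libraries G0 and G14.5 also entered late against early gestation, so genes named there are not tested anew on separate libraries. Abca17 and Crip1, named above for late gestation, rose by 8.54 and 7.30 on the log2 scale (n = 2 against 2 libraries, edgeR quasi-likelihood, adjusted p of 0.00335 and 0.00357). Crybb3, a crystallin gene, and Nedd9 rose by 5.87 and 5.58. Prlr rose from 320.5 ± 8.71 to 2272.6 ± 144.6 CPM, Ghr by 3.23, Cp by 2.59, Itih4 by 2.52, and A1bg, a female-biased plasma glycoprotein gene, from 109.7 to 2597.4 CPM. Pnpla3, a lipid remodelling gene, rose by 4.13, Fads1 by 1.76, Tat of tyrosine breakdown by 1.76, and Mvd and Fdps of the mevalonate pathway by 2.52 and 1.41. Ccna2 and Ccnb1, the cyclins of S phase and mitosis, rose from 0.148 to 5.56 CPM and from 0.0774 to 7.19 CPM. Per3, a period gene of the circadian clock, changed by -4.39, Rgs16, a regulator of G protein signalling, by -4.13, and Mfsd2a, a lysophospholipid transporter gene, by -3.73. Ddah1 and Abcc3 changed by -3.72 and -3.55, the periportal genes Etnppl and Hsd17b13 by -2.59 and -2.66, and Cyp2c37 and Cyp3a11 by -1.71 and -2.10. Among other clock genes, Dbp had 0.812 CPM against 18.4, Nr1d2 20.5 against 94.1, and Arntl 14.6 against 1.23. Il6st had 54.7 and 44.0 CPM, and Acss2 151.1 and 101.9 CPM (adjusted p of 0.486 and 0.429).

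For G14.5 against G0, wild type, of 19541 genes tested, 552 were higher and 266 lower at G14.5 (edgeR quasi-likelihood). The G2/M list had 19 of 24 genes higher with a median log2 fold change of 5.05 (camera, adjusted p = 4.69e-41, and 0.313 with an estimated correlation). The erythroid markers moved the same way, with 6 of 6 genes above 0, 1 of them called, and a median of 2.08 (adjusted p = 0.00368, and 0.422 with an estimated correlation). The clock list had 9 of 17 genes lower and 3 higher, and periportal genes 6 of 18 lower and 1 higher (adjusted p of 2.45e-05 and 2.02e-07, each 0.313 with an estimated correlation). With library size as the only scaling, 422 genes were higher and 463 lower, a share of 47.7% higher in place of 67.5%, and the median of all genes moved by -0.22. DESeq2 called 1930 genes and a fit with cohort as a term 534. The count fell to 379 without G14.5, 268 without G14.5_Il6st_WT and 417 without G0_Il6st_WT.

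The Il6st_HMKO libraries were compared with wild type at G0 and G14.5 to ask whether this receptor subunit matters for the response to pregnancy. At G14.5, Sult2a3, a sulfotransferase gene, had 20.6 CPM in Il6st_HMKO (n = 1 library) and 0.502 ± 0.116 CPM in wild type (n = 2), a log2 fold change of 5.35 (edgeR quasi-likelihood, adjusted p = 0.0207). Serpinb1a, an inhibitor of neutrophil proteases, had 16.3 and 1.59 CPM, a log2 fold change of 3.34 (adjusted p = 0.0207). Both genes were chosen after their values were seen, and neither passed without G14.5 or without G14.5_Il6st_WT, when 0 genes were called. The 2 wild-type libraries come from different cohorts, and with cohort as a term in the fit of Il6st_HMKO against wild type at G14.5, Sult2a3 and Serpinb1a changed by 5.10 and 3.38 at an adjusted p of 0.122 each, so 0 genes were called. The cohort term is 1 shift common to all stages of the fit, so it does not adjust for differences that vary by stage. Ccnb1, also chosen afterwards, had 1.53 and 7.19 CPM. The G2/M list had a median log2 fold change of -2.11, with 12 of 24 genes lower when adjusted over the list alone and 0 over all genes (camera, adjusted p = 1.13e-22, and 0.459 with an estimated correlation). The erythroid markers had a negative median too, of -3.10, with 0 of 6 genes above 0 (adjusted p = 0.00145, and 0.459 with an estimated correlation). Of these markers 0 were called, over all genes or over the list alone. The endothelial and stellate cell markers had medians of 1.96 and 1.12 (adjusted p of 2.77e-11 and 0.000299, each 0.459 with an estimated correlation). Their summed levels were 62.7 and 23.7 CPM in G14.5_Il6st_HMKO, 27.9 and 13.6 CPM in G14.5_Il6st_WT, and 10 and 4.5 CPM in G14.5. The 2 wild-type libraries thus differed in these markers too. The neutrophil markers had 3 of 4 genes higher when adjusted over the list alone (adjusted p = 6.64e-05, and 0.459 with an estimated correlation). Their summed level was 4.1 CPM in G14.5_Il6st_HMKO and 0 CPM in both wild-type libraries.

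Of 19541 genes, 2 were called at G14.5, with 795 at an unadjusted p below the threshold and 77 by DESeq2. At G0, edgeR called 0 genes, with 1311 at an unadjusted p below the threshold and 132 by DESeq2. The endothelial, stellate and Kupffer cell markers had negative medians at G0, of -2.67, -1.40 and -5.11, and so had the erythroid markers, at -7.96 (camera, adjusted p of 0.000887, 0.00986, 0.00553 and 0.0530, each 0.731 with an estimated correlation). Summed Kupffer and erythroid marker levels were 0.4 and 3.9 CPM in G0_Il6st_HMKO, 0.3 and 3.4 CPM in G0_Il6st_WT, and 15.2 and 23.8 CPM in G0. By these sums G0_Il6st_HMKO lay below G0 but not below G0_Il6st_WT. A sum can be carried by 1 gene, so it does not show where a median comes from. The endothelial sums were 6.3, 7.1 and 13.7 CPM in the same order, and the stellate ones 8.6, 13.5 and 10.6 CPM. For the difference between the 2 genotype effects, edgeR called 0 genes, with 1119 at an unadjusted p below the threshold and 146 by DESeq2. The number expected by chance is 977 in each of these 3 tests. Il6st itself differed by -0.18 at G0 and -0.19 at G14.5 on the log2 scale, with a difference of -0.01 between them. Library size as the only scaling moved the median of all genes by -0.11 at G0 and by 0.16 for the difference. At least 10 reads of the insulin gene Ins2 were found in 66.8% of cells of G0_Il6st_HMKO, 8.0% of G0_Il6st_WT and 0.5% of G0. The fit was not repeated without such cells. In the simulation of this design at G14.5, 6% of genes changed 2-fold were recovered, at G0 7%, and for the difference 0%, with 2% of those changed 4-fold, so such effects would mostly be missed with 1 HMKO library.

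Acss2_HMKO was compared with wild type at P4L to ask what this acetate-activating enzyme does in lactation, when its transcript is high. Acss2 itself had a log2 fold change of -1.11 with a standard error of 0.42 (n = 1 against 2 libraries, edgeR quasi-likelihood, adjusted p = 0.272). Idi1, an isomerase of the mevalonate pathway (chromosome 13, 8885501 to 8892451), fell from 42.7 ± 4.15 to 5.18 CPM, a log2 fold change of -3.03 (adjusted p = 0.0322). Slc17a8, a vesicular glutamate transporter gene, had 0.147 against 3.03 CPM (adjusted p = 0.0322). Rps2-ps13, a pseudogene whose reads may be shared with Rps2, had 41.4 against 0.736 CPM (adjusted p = 0.000818). With cohort as a term in the fit of Acss2_HMKO against wild type at P4L, Rps2-ps13 alone was called, and Idi1 and Slc17a8 had an adjusted p of 0.190 and 0.167. Hmgcs1, of the first committed steps of sterol synthesis, had 251.8 against 2044.4 CPM (adjusted p = 0.160). Saa1 and Lcn2, which inflammation induces in liver, had 5572.2 against 243.5 CPM and 209.0 against 11.5 CPM, and Ccnb1 had 0.0368 against 3.79 CPM, all short of the threshold. Slc17a8, Rps2-ps13, Hmgcs1, Saa1, Lcn2 and Ccnb1 were chosen after their values were seen. Il6st had 48.7 and 40.5 CPM.

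Of 19541 genes tested in the Acss2_HMKO comparison, 1 was higher and 2 lower (edgeR quasi-likelihood), with 3022 at an unadjusted p below the threshold, 977 expected by chance, and 1001 by DESeq2. The acute phase list had 21 of 29 genes higher and 1 lower when adjusted over the list alone, but 0 over all genes (camera, adjusted p = 2.27e-25, and 0.311 with an estimated correlation). Likewise 14 of 25 cholesterol synthesis genes and 20 of 24 G2/M genes were lower (adjusted p of 2.63e-15 and 2.46e-21, and 0.311 and 0.369 with an estimated correlation). The erythroid markers had a median of -5.12 with 0 of 6 genes above 0 (adjusted p = 0.123, and 0.604 with an estimated correlation), and their summed level was 1.3 CPM in P4L_Acss2_HMKO, 14.4 CPM in P4L_Acss2_WT and 1.6 CPM in P4L. The fatty acid synthesis list, which holds Acss2, had 3 of 19 genes lower and 1 higher when adjusted over the list alone. The mean log2 level of the G2/M list was 0.55 in P4L_Acss2_HMKO, 1.72 in P4L_Acss2_WT and 1.63 in P4L. It ranged from 0.47 to 2.09 in the lactating libraries of the course, so P4L_Acss2_HMKO lay within their spread. For cholesterol synthesis the levels were 6.04, 7.02 and 7.43, and 6.26 to 7.43 in the lactating course libraries. Library size as the only scaling moved the median of all genes by -0.26. Without P4L_Acss2_WT 1 gene was called, and in simulated data 2% of genes changed 2-fold were recovered.

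Gestation and lactation were set side by side to ask whether they change the same genes. Over 3996 genes with at least 20 CPM, the log2 fold changes of late against early gestation and of lactating against non-lactating had a Pearson r of -0.06 and a Spearman rho of -0.10. These are correlations across genes, which are not independent replicates. The groups compared share no library. The fit of late against early gestation, however, took its spread from all 21 course libraries, lactating and non-lactating ones included. Of 339 such genes called in gestation, 165 had the same sign in lactation, or 48.7%. With 0 edgeR calls in lactation no call was shared. By DESeq2, a comparison chosen after seeing the data, 47 genes were higher in both (15.7 expected from independent lists) and 25 lower in both (9.7). Another 23 were higher in late gestation and lower in lactation (10.8) and 19 the reverse (14.1). Each number lay above its expectation, also where the directions were opposite. The lists are not independent, since the lactating and non-lactating libraries entered both fits.

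Reads of G2/M genes were counted per cell to follow the mitotic transcripts through the course. In mid and late gestation 39.9% ± 14.2 of cells (SD, n = 6 libraries) had reads of at least 3 of the 24 genes, and in early gestation 41.2% ± 14.4 (n = 4). The highest share was 63.2% in G8.5 and the lowest of these 10 was 23.4% in G18.5. G0 had 25.9% (82 of 317 cells, exact 95% interval 21.1 to 31.1), and G0_Il6st_WT had 10.9%, so libraries of the same stage differed. After lactation was stopped the shares were 34.8% on day 1, 17.4% on day 2, 9.6% on day 4 and 5.2% on day 7. G14.5_Il6st_WT had 42.8% and G14.5_Il6st_HMKO 36.0%, and P4L_Acss2_WT had 39.7% and P4L_Acss2_HMKO less, in 44 of 231 cells. With reads of at least 8 genes, a limit chosen after seeing the data, the shares were 9.0% in G14.5_Il6st_WT and 2.5% in G14.5_Il6st_HMKO, 3.3% in P4L_Acss2_WT and 1 of 231 cells in P4L_Acss2_HMKO. At that limit mid and late gestation had 3.3% ± 3.0 and early gestation 2.2% ± 3.0. Without thinning, the share in mid and late gestation was 53.8%. No test was made between libraries from cells, stray reads from other wells are not excluded, and no cycling is read from these shares.

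Reads of pancreatic hormone genes appeared in part of the cells of some libraries. Ins2, which encodes insulin, had 7289 CPM in P7L, 1045 CPM in G0_Il6st_HMKO, 449.5 CPM in G8.5 and 0.0465 CPM in P4L_Acss2_WT. In P7L, 368 cells or 73.5% had at least 10 Ins2 reads, and the longest run of cell numbers without such reads went from 186 to 318. In all, 1879 cells of the 31 libraries had at least 10 reads of this gene.

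**Figure D3:**
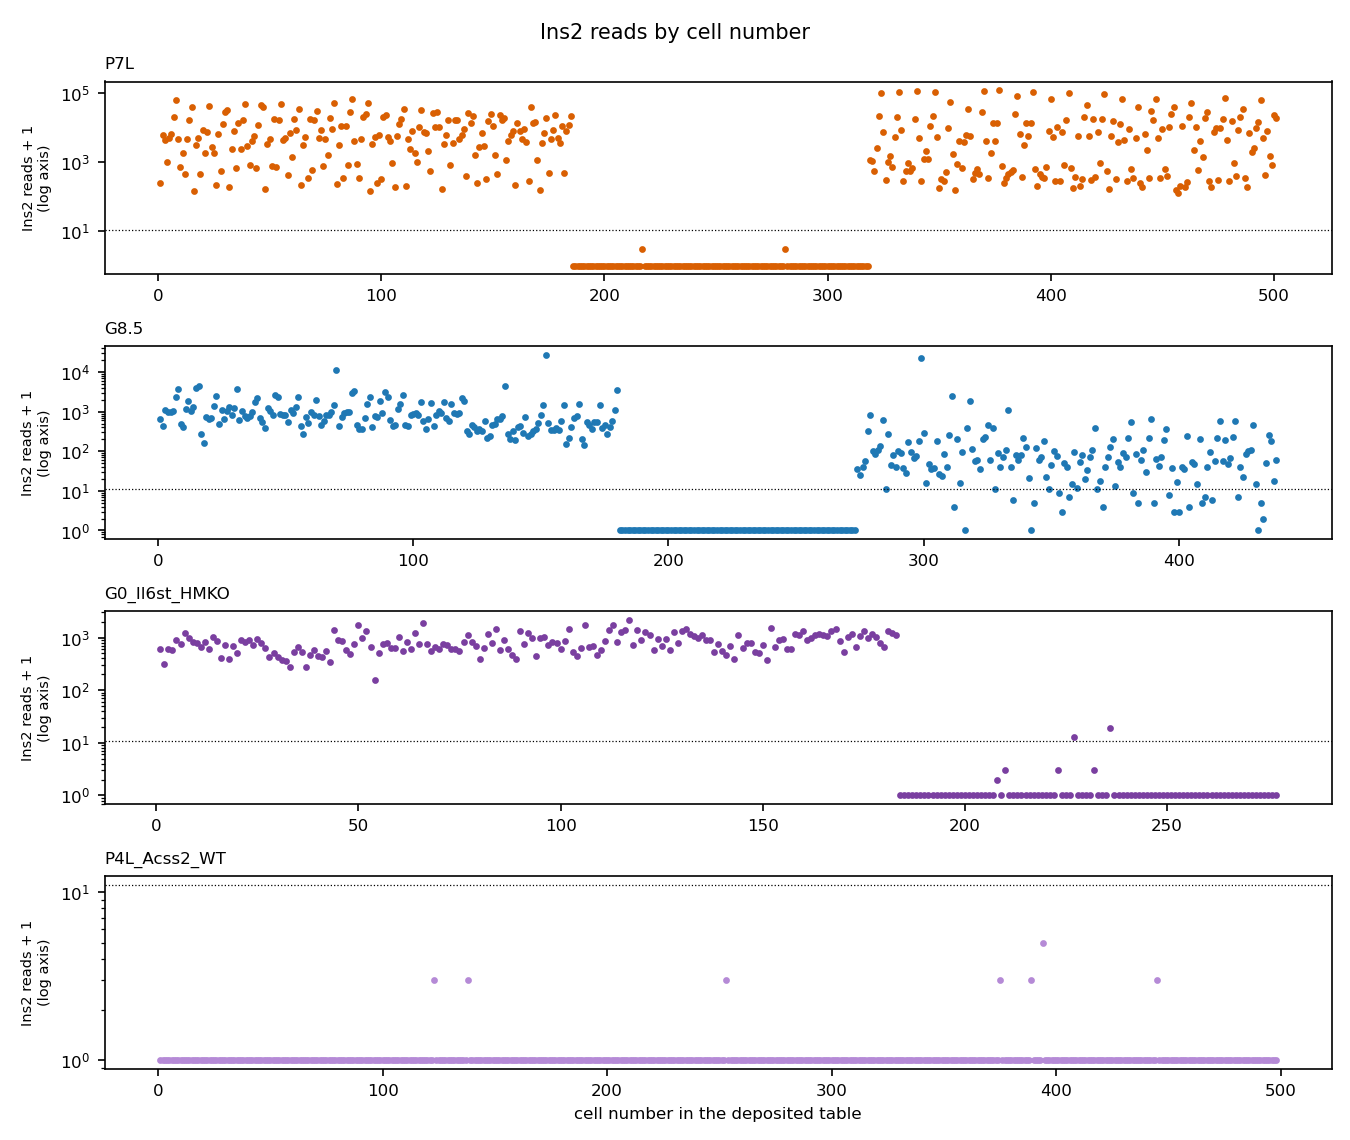
Ins2 reads per cell, plus 1, on a log axis against cell number within the library for P7L, G8.5, G0_Il6st_HMKO and P4L_Acss2_WT. Each point is 1 cell and the dotted line marks 10 reads. In P7L a block of 133 neighbouring cells lies below the line.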

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

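The tests of the insulin reads and of the cohort, the stop of lactation, the oxidative phosphorylation genes and the clock genes were chosen after the result was seen. The length test of the ribosomal protein genes was not. Where a group had 4 to 10 libraries, each gene of a comparison was examined for a library standing far apart. This was the case in 10 of 136 groups, against 6.8 by chance, since about 1 in 20 groups is picked out with no effect.

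In early gestation, G0 had 521.2 CPM of Serpina6 against 354.4 to 378 in the other libraries. G5.5 had 4.11 CPM of Peg3 against 6.32 to 6.72. Among lactating libraries, P7L had 4.14 CPM of Crip1 against 0.71 to 1.85. P14L had 1141.3 CPM of Pigr against 847 to 945. P1L had 184.2 CPM of Gulo against 47.6 to 95.7. It also had 104.4 CPM of Slc1a2 against 13.1 to 46.4. Among non-lactating libraries, P7NL had 525.2 CPM of Acss2 against 114 to 159. P14NL had 675.9 CPM of Mt1 against 149 to 211. After lactation was stopped, day 1 had 244.3 CPM of Orm3 against 77.3 to 104. Day 2 had 1259.9 CPM of Itih4 against 1892 to 1997. Outside the genes, ERCC spike-in sequences drew 688 reads in all libraries, 299 of them in G14.5_Il6st_WT, and no comparison used them.

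Insulin genes had many reads in part of the hepatocytes of some libraries, with 7289 CPM of Ins2 in P7L. Expression by lactating hepatocytes is argued against, since the higher level of P14L and P4L_Acss2_WT, which lactate too, was 0.121% of that in P7L. A few islet cells picked by mistake are argued against as well, since the 3 highest cells held 7.8% of the Ins2 reads of P7L. Reads of islet cells carried into blocks of wells stay open as a candidate explanation. In P7L, 99.6% of neighbouring cell numbers were alike in having these reads, against at most 67.0% in 10000 shuffled orders (permutation p = 0.0001, the smallest they can give). Of the 17 libraries so tested, G12.5 showed no such blocks, with 91.4% against a shuffled mean of 91.3% (permutation p = 0.5873). G3.5, P2L, P14L, P2NL and P7NL lay below their highest shuffled share but above their shuffled mean. Their permutation p was 0.0016, 0.0021, 0.0004, 0.0008 and 0.0006. The other tested libraries lay above their highest shuffled share. The labels mention no pancreas sample, and they do not state whether cell numbers follow the plate. Ins2 reads rose and fell at an even spacing over part of P7L. Cells 23, 31, 39, 47, 55, 63, 71, 79 and 87 had 29520 to 64313 reads. Cells 16, 32, 48, 64 and 80 had 139 to 233. Such a repeat would go with cell numbers that follow the wells in order. It was picked out by eye and was not tested.

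Part of the ribosomal protein and oxidative phosphorylation genes, 22 of 86 and 10 of 79, were higher after lactation was stopped, and neither list passed with an estimated correlation (adjusted p of 0.652 for both). A bias by transcript length was examined with random lists matched on level and on the merged length of all annotated exons of a gene. The ribosomal median of 0.61 over 85 genes stood at percentile 100. The random lists had a median of 0.32 themselves, so part of the rise may be shared. Oxidative phosphorylation stood at percentile 92.99. Merged exons can be longer than the transcript expressed, and the random lists were drawn gene by gene, without the correlation within a list. The test therefore cannot decide on a length bias, which stays open for both lists. A difference between sets of libraries made apart may also contribute, since P4L_Acss2_WT, the 1 lactating wild-type library outside the course, had a mean log2 level of 7.7 and the 6 lactating libraries of the course 7.17 to 7.55. The other wild-type libraries outside the course differed both ways, with 8.04 in G14.5_Il6st_WT against 7.66 in G14.5 and 6.99 in G0_Il6st_WT against 7.61 in G0. The stop of lactation cannot be told apart from such a difference between sets of libraries. The level was 7.68, 7.83, 8.07 and 8.20 on days 1, 2, 4 and 7 after the stop, with 3 of the 4 above P4L_Acss2_WT. In the course, P1NL, P2NL, P7NL and P14NL had 7.16, 7.14, 7.31 and 7.41, none above the range of its lactating libraries. The absence of lactation alone thus did not go with a higher level there. Which libraries were made together is not said in the labels.

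Clock genes differed between G14.5 and G0, with Dbp at 0.812 against 18.4 CPM. A difference in the hour of collection may explain it, since Dbp differed 26.4-fold among the early and 14.1-fold among the late libraries. A steady shift with gestation cannot be told apart from it, since 2 late gestation libraries had more Dbp than the lowest early one, but a shift on top of such variation would overlap too. The labels give no hours, so both stay hypotheses.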

How the results depend on the processing

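Tests without insulin-read cells, at a mean of 1 CPM, of shared DESeq2 calls and at 8 G2/M genes were chosen after the result was seen. No gene value reversed. Of gene values with a library left out, 909 of 1122 stayed on their side of the threshold, 205 lost a call and 8 gained one, and under the other settings 1478 of 1556 stayed, 45 lost a call and 33 gained one. Of the 205 losses, 138 belong to lactation stopped against lactating, where 40 of 44 genes lost their call without some library. The cause of a change was not tested except where named.

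Counts of genes past the threshold moved by more than 1.5 times as follows. With DESeq2 they were 2011 for late against early gestation, 1780 for lactating against late gestation, 424 for lactating against non-lactating, 3555 for lactation stopped against lactating, 1930 for G14.5 against G0, wild type, 132 and 77 for Il6st_HMKO at G0 and G14.5, 146 for their difference (interaction), and 1001 for Acss2_HMKO against wild type at P4L. With library size as the only scaling they were 3422 for late against early gestation, 1533 for lactating against late gestation and 2 for the Il6st_HMKO difference. With no expression filter they were 137 for lactating against non-lactating, 2030 for G14.5 against G0, 496, 247 and 408 for Il6st_HMKO at G0, at G14.5 and their difference, and 1074 for Acss2_HMKO. With thinned cells they were 8 for lactating against non-lactating, 0 for Il6st_HMKO at G14.5 and 1 for Acss2_HMKO. With cohort as a term they were 534 for G14.5 against G0, 1 and 0 for Il6st_HMKO at G0 and G14.5, and 1 for Acss2_HMKO. A mean of 1 CPM gave 10 for lactating against non-lactating and 1 for Acss2_HMKO. Without insulin-read cells there were 598 for late against early gestation and 1112 for lactation stopped. A spline over gestation day gave 1680, all 6 lactating libraries 3013, and leaving out the tenth of cells with the fewest reads 2 for the Il6st_HMKO difference.

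With 1 library left out, counts ranged from 461 to 1120 for late against early gestation, 3.3e+02 to 973 for lactating against late gestation, 0 to 9 for lactating against non-lactating, 63 to 1835 for lactation stopped against lactating and 268 to 622 for G14.5 against G0, wild type. They were 0 for Il6st_HMKO at G0, at G14.5 and for the difference, and 1 to 2 for Acss2_HMKO. On a matched day the partner library drops out too, so fewer libraries remain.

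List calls numbered 125 at the preset correlation and 1 with an estimated one. Shared calls of gestation and lactation were 114 with DESeq2. The share of cells with G2/M reads in mid and late gestation was 71.6% at 2 genes and 3.3% at 8. No analysis paired by replicate number was possible because each label carries number 1, and lactating against non-lactating was blocked by day instead. Leaving out the lone HMKO library and sums per animal were not run. Thinned cells hold fewer reads, and with them 1 of the 3 counts that moved rose and 2 fell.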

Other observations

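The tests of other splits of the libraries were planned, and the tests weighed for insulin reads, ribosomal protein genes and clock genes were named where they stand. For late against early gestation the real split called 1022 genes, 1 of 35 splits reached that, and the highest other called 266. For lactating against late gestation there were 908 genes in the real split, with 1 of 84 splits as high, and 159 in the highest other. For lactation stopped against lactating the real split called 1832 genes, with 1 of 35 splits as high, and 1 gene in the highest other. A share of 1 in 35 or 1 in 84 is the smallest these splits can give. The other splits mix libraries of both groups, which widens the spread within a group and lowers their counts. The splits therefore exclude neither chance nor a difference in how the libraries were made. For lactating against non-lactating the splits decide nothing, since the real one called 0 genes, which each of the 32 splits that could be fitted reaches by construction, and the highest other called 15. Whether the 4 libraries after lactation was stopped were made together, apart from P4L, P7L and P14L, is not stated in the labels.

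Libraries of the same stage from different cohorts had a Pearson r over 4233 genes of 0.944 at G0, 0.975 at G14.5 and 0.956 at P4L on log2 CPM. The highest of all pairs was 0.989 for days 4 and 7 after lactation was stopped. These are correlations across genes, which are not independent replicates.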
